A study of Chromochloris zofingiensis with 6 samples.

How the data were processed

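RNA-seq was analysed from 6 samples of the green microalga Chromochloris zofingiensis (strain ATCC 30412), 3 grown without levofloxacin and 3 grown with 10 mg/L levofloxacin, a fluoroquinolone antibiotic whose bacterial targets are DNA gyrase and topoisomerase IV. Per the labels' protocols, the cells were kept in the dark at 25 °C on a shaker at 150 rpm, in a medium with 30 g/L glucose, so that growth was heterotrophic. Total RNA was taken from 100 mL of culture on day 15, and libraries were made from 1 μg of it with the NEBNext Ultra RNA kit, per the labels' protocols. The labels number the samples 1 to 3 in each group and do not say whether the numbers stand for separate cultures, so the p-values measure the spread between these samples, which may be in part technical.

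The deposited count table holds whole-number read counts for 15364 gene IDs, 1 column per library. HISAT2 2.0.6 and HTSeq 0.6.1 are named in the submitters' processing notes, while the genome build, the annotation and the strand setting are not given in the sources used here. Without a stated strand setting, reads from overlapping or antisense genes cannot be told apart, and near-identical copies may share reads. The deposited FPKM table (fragments per kilobase of gene and 1e6 assigned reads) holds 15369 IDs, 5 of which are outside the count table used here. Each FPKM value was tested against the counts: a single length per ID and a single total per library gave every FPKM value from its count to within 4.77e-06 percent. The totals behind the FPKM values exceed those of the count table by 0.00942% on average. The deposited FPKM values are therefore the same counts divided by gene length and by the reads assigned to genes. Of the 15199 lengths recovered in this way, 99.7% are multiples of 3, so they are coding lengths without untranslated regions.

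The files do not pair the IDs with gene names or descriptions, and no annotation was used here. The 20 gene lists planned from descriptions (photosystems, lipid and carotenoid synthesis, antioxidant and detoxifying enzymes and others) could not be formed, and 0 of them were run. At most 2 IDs that rose and 2 that fell are printed. The rule for them, fixed before the data were examined, took the 2 highest and the 2 lowest log2 fold changes among IDs with adjusted p under 0.05, a mean of at least 5 CPM (counts per 1e6 assigned reads) and no overlap between the libraries of the groups. The part of each ID before the gene number was used as a place label. Cz01 to Cz19 are read as the 19 chromosomes, CzCPg as the chloroplast genome, CzMTg as the mitochondrial genome and UNPLg as unplaced sequence, after the naming of the species' published annotation, which the files themselves do not state. The order of IDs is taken as the order of genes, which could not be checked against coordinates.

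Counts were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (14236 IDs kept and 1128 left out), TMM normalisation, and the quasi-likelihood F test of levofloxacin against control over all 6 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. Standard errors of log2 fold changes are the fold change divided by the square root of F. CPM values use the TMM-scaled library sizes, and log2 CPM a prior count of 2. Calls per ID prefix were compared with calls elsewhere by Fisher's exact test (two-sided, 44 tests over 22 prefixes of at least 20 tested IDs, adjusted together). Pairs of neighbouring tested IDs called in the same direction were set against 10000 shuffles of the calls. Tests of prefixes as sets used fry and camera from limma 3.58.1. Genes are not independent replicates, so tests across genes describe these libraries. Intervals of shares are exact binomial 95% intervals and floors are 3 counts; both cover counting error only, since reads carry no molecular identifiers.

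On counts simulated from the means, dispersions and totals of these libraries over 14236 IDs, edgeR recovered 8% of planted 1.5-fold changes, 58% of 2-fold, 90% of 3-fold and 94% of 4-fold changes in this comparison, with 9 false calls. With 50 IDs planted per fold size, few IDs were called, so the adjusted threshold was stricter in the simulation than in the comparison itself and the shares do not carry over to it. Each ID was also simulated independently and with the same dispersion in both groups. In the libraries themselves the biological coefficient of variation was 24.9% among controls and 10.9% with levofloxacin. The 9 false calls therefore do not carry over to the comparison either. The positional tests, run on calls placed at random, gave a ratio of 0.837 to the shuffles and 0 prefix calls.

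Replicates of a group differed by far more than counting noise: the chi-square statistic per degree of freedom between pairs ran from 9.65 to 198, so no library was treated as deposited more than once. Libraries with the same number in both groups deviated from their group means with correlations of 0.16, 0.05 and 0.04 across genes for numbers 1, 2 and 3. As not all exceeded 0.1, the numbers were not taken to pair the samples. Alternatives were other normalisations (RLE, upper quartile, library totals), other filters, DESeq2 1.42.0, limma-voom with and without sample weights, limma on log2(FPKM + 1) and log2(FPKM + 0.1), other thresholds, the replicate number as a block, and leaving out each library. All were chosen before the data were examined except the sample weights, the set tests of prefixes, the use of the filters and FPKM scales on the named IDs, and the use of these settings on the prefix, neighbour and length results. Of the latter, DESeq2 and the 2-fold calls for prefixes and neighbours, and DESeq2 and the 10-count filter for length, had been chosen before. Counts in cultures grown under light were not analysed here.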

Results

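Gene expression was measured by RNA-seq in heterotrophic cultures of C. zofingiensis, an oil-rich green alga, after 15 days with 10 mg/L levofloxacin (n = 3) or without it (n = 3). The comparison asks how transcription differs in cells kept with the antibiotic, within a study of how this alga removes levofloxacin. The reads assigned to genes numbered 29311743, 36223195 and 34343529 in control replicates 1, 2 and 3, and 28482776, 33005815 and 32045754 in levofloxacin replicates 1, 2 and 3. Between 14124 and 14236 gene IDs had at least 10 counts in each library. The files identify genes by ID alone, so the results are given for IDs and for groups of IDs by genome compartment.

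The levofloxacin libraries had expression profiles close to each other, and the control libraries did not. Pairs of levofloxacin libraries had Spearman correlations of log2 CPM across genes of 0.993 to 0.996. Pairs of control libraries ranged from 0.961 to 0.984, and pairs of a control and a levofloxacin library from 0.928 to 0.979. Control replicate 2 was closer to each levofloxacin library (0.976 to 0.979) than to control replicate 1 (0.961), and closest to control replicate 3 (0.984). The biological coefficient of variation was 24.9% among control and 10.9% among levofloxacin libraries. The first principal component held 68.0% of the variance and separated the groups, with the levofloxacin libraries between 33.8 and 41.5 and the controls at -66.5 (replicate 1), -9.03 (replicate 2) and -36.9 (replicate 3). The 10 most abundant IDs took 6.91% of the counts in control replicate 1, 4.31% in control replicate 2 and 5.18% in control replicate 3, against 4.21 to 4.53% in the levofloxacin libraries.

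**Figure D1:**
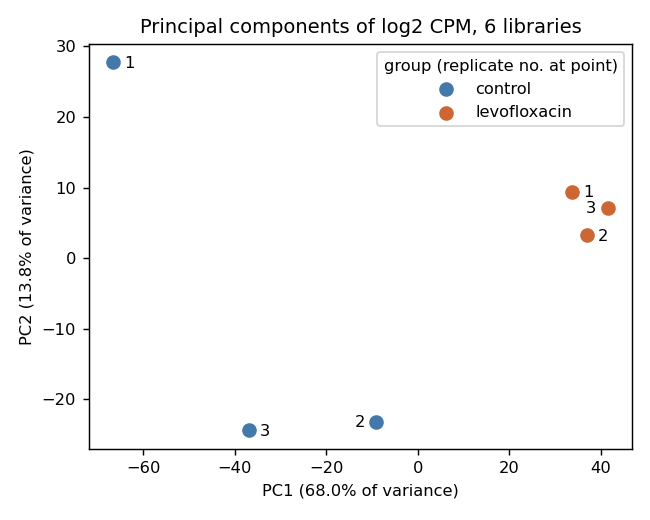
Principal components 1 and 2 of log2 CPM (14236 tested IDs), each point a library, coloured by group and marked with its replicate number. The 3 levofloxacin libraries lie together between 33.8 and 41.5 on the first component, and the controls are spread from -66.5 to -9.03.

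Levofloxacin libraries differed from controls in the expression of 3149 of 14236 tested IDs (22.1%), of which 1432 rose and 1717 fell (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change was 0.72 among the IDs that rose and -0.86 among those that fell. By at least 2-fold 357 IDs rose and 720 fell, and by at least 4-fold 51 rose and 195 fell, while 2072 of the calls were under 2-fold. The excess of decreases was not kept without levofloxacin replicate 2, where 249 IDs rose and 240 fell by at least 2-fold and 477 rose and 389 fell in all. With limma on log2(FPKM + 1), 300 rose and 371 fell by at least 2-fold, so the share of decreases was 55.3% in place of 66.9%. Among all calls in that test 1204 rose and 1166 fell. Limma-voom on the counts gave nearly equal numbers, with 1411 higher and 1416 lower. By at least 2-fold it gave 368 higher and 515 lower (58.3% lower). In 45.3% of all tested IDs the libraries of the groups did not overlap, where chance gives 10% on average. IDs vary together, so this share is a description and not a test of treatment. The number of calls changed with the libraries included: it was 248, 866 and 240 without levofloxacin replicate 1, 2 or 3, 1171 without control replicate 3, and 3632 and 4402 without control replicate 1 or 2. The 2-fold calls came to 205, 489 and 200 without levofloxacin replicate 1, 2 or 3, 590 without control replicate 3 and 1681 without control replicate 2.

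**Figure D2:**
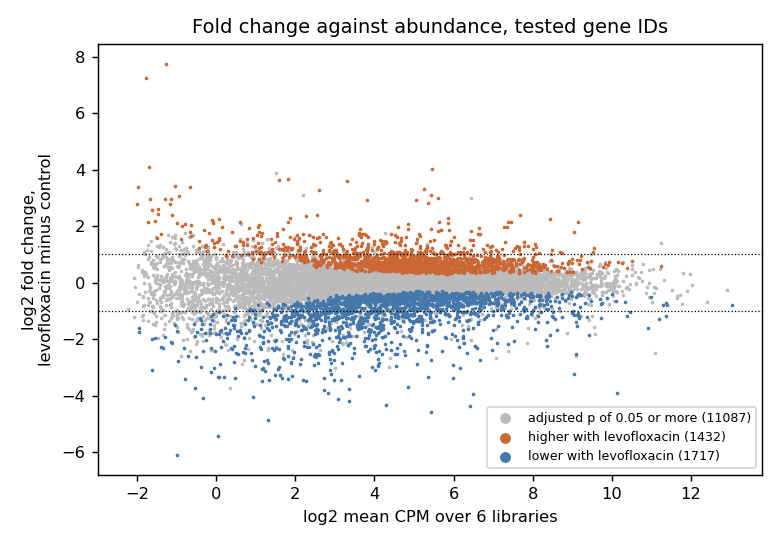
Log2 fold change (levofloxacin minus control) against log2 mean CPM for the 14236 tested IDs, with the 1432 higher and 1717 lower calls in colour and dotted lines at 2-fold. Decreases of more than 4-fold (195 IDs) outnumber increases of that size (51 IDs).

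Among IDs with a mean of at least 5 CPM and no overlap between the groups, the largest increase was that of Cz04g39120, a gene with a coding length of 456 bases, which rose from 5.03 ± 1.36 CPM (SD, n = 3) in controls to 82.1 ± 5.34 CPM with levofloxacin, a log2 fold change of 4.03 ± 0.21 (SE; edgeR, adjusted p = 0.00032). The mitochondrial ID CzMTg00020 (coding length 681 bases) rose from 1.53 ± 0.395 to 18.3 ± 4.66 CPM, a log2 fold change of 3.59 ± 0.27 (SE; adjusted p = 0.0014). Its counts were 50, 42 and 55 in the controls and 474, 500 and 775 in the levofloxacin libraries.

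Among the same IDs the largest decrease was that of Cz14g07020, with a coding length of 4251 bases, which fell from 82.7 ± 11.1 to 3.48 ± 0.75 CPM, a log2 fold change of -4.57 ± 0.19 (SE; edgeR, adjusted p = 0.00019). UNPLg00344 (coding length 615 bases) fell from 19.4 ± 21.3 to 1.07 ± 0.59 CPM, a log2 fold change of -4.19 ± 1.00 (SE; adjusted p = 0.026). Its control counts were 1156, 90 and 427, against 51, 21 and 27 with levofloxacin, so control replicate 1 held most of them. Without control replicate 1 its log2 fold change was -2.82. Its call was lost in limma-voom (adjusted p = 0.15), in limma on log2(FPKM + 1) (adjusted p = 0.054) and without control replicate 3 or any levofloxacin library (edgeR, adjusted p = 0.059 to 0.10).

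Few transcripts were detected in a single group. In 2 IDs all control libraries had 0 counts while each levofloxacin library had at least 10. Counts in levofloxacin replicates 1, 2 and 3 were 22, 34 and 23 for the first and 22, 16 and 17 for the second. Over the group totals this is at least 28.1-fold and at least 19.6-fold higher than the limit of 3 counts that the pooled controls allow. In the opposite pattern, 0 IDs had at least 10 counts in each control and 0 counts with levofloxacin, and 1 ID did at a minimum of 5 counts.

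Mitochondrial transcripts changed in both directions. Of 22 mitochondrial IDs (prefix CzMTg), all of them tested, 6 rose by 2.64-fold to 12.7-fold, 5 fell by 1.76-fold to 5.28-fold and 11 did not pass the threshold. As a set they changed in either direction more than replicate error (fry, limma's rotation test, mixed adjusted p = 0.00011 over 3 sets), while the test for a common direction was not passed (adjusted p = 0.60). The reads of all CzMTg IDs together came to 272 ± 56.0 per 1e6 assigned reads (SD, n = 3) in controls and 290 ± 76.3 with levofloxacin, a difference within the replicate spread (exact permutation test, two-sided, p = 0.70, where 3 against 3 cannot go below 0.10). The higher and lower calls numbered 1 and 3 without levofloxacin replicate 1 and also without levofloxacin replicate 3, 3 and 3 without control replicate 3, and 10 and 5 without control replicate 1. Without levofloxacin replicate 2 they numbered 6 and 3.

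Reads assigned to chloroplast IDs were few, and their total did not differ between the groups beyond the spread of the controls. Selection of transcripts by their tails during library preparation was not examined, so few reads need not mean few transcripts in the cells. Of 73 chloroplast IDs (prefix CzCPg) 25 had enough counts to test, of which 6 fell by 4.89-fold to 10.7-fold, 0 rose and 19 did not pass the threshold. The fold change was negative in 22 of the 25 and positive in 3. The chloroplast total was 111 reads per 1e6 assigned reads in control replicate 1 (exact 95% interval 107 to 115), 60.4 in replicate 2 (57.9 to 63.0) and 21.8 in replicate 3 (20.2 to 23.4). With levofloxacin it was 15.0 (13.6 to 16.5), 21.4 (19.8 to 23.0) and 26.5 (24.7 to 28.3). Control replicate 3 thus lay within the levofloxacin range (exact permutation test, two-sided, p = 0.20). The set did not pass limma's fry test for a common direction (adjusted p = 0.27) or its mixed test (adjusted p = 0.080, and 0.0080 without control replicate 3). Limma's camera gave p = 0.00047 with a preset correlation of 0.01, a call lost with an estimated correlation (p = 0.42 with an estimated correlation). The number of lower calls was 14 with DESeq2, 1 with limma-voom, 3 where at least 10 counts were required in every library, 3 without control replicate 1, 11 without control replicate 3, 0 without levofloxacin replicate 1 or 3, and 1 without levofloxacin replicate 2.

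**Figure D3:**
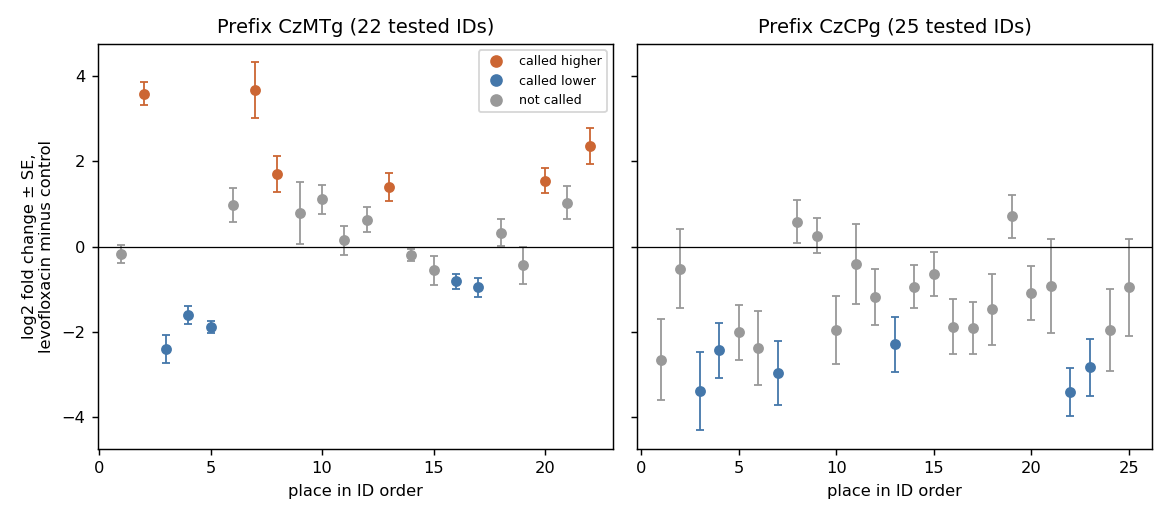
Log2 fold change (levofloxacin minus control) with its standard error for each tested mitochondrial ID (left, 22 IDs) and chloroplast ID (right, 25 IDs), in ID order. Called IDs are in colour: 6 mitochondrial IDs rose and 5 fell, while the 6 called chloroplast IDs all fell.

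Among chromosomes, Cz18 had the highest share of IDs that rose. On it 42 of 217 tested IDs (19.4%) rose, against 9.92% of IDs elsewhere, an odds ratio of 2.18 with a 95% interval of 1.51 to 3.08 (Fisher's exact test, two-sided, adjusted p = 0.0014 over 44 tests). The median log2 fold change on Cz18 was 0.08. Limma's fry gave an adjusted p = 0.026 for a common direction, which was lost without control replicate 1 (0.14) or 3 (0.055) and without levofloxacin replicate 1 (0.10) or 3 (0.11), and camera p = 0.071 against other genes (p = 0.10 with an estimated correlation). No other prefix passed for higher or lower calls. Among calls of at least 2-fold, Cz18 (13 higher, odds ratio 2.53, adjusted p = 0.037), Cz17 (15 of 241 higher, odds ratio 2.65, adjusted p = 0.019), the mitochondrial IDs (6 higher, odds ratio 14.8, adjusted p = 0.00056) and the chloroplast IDs (6 lower, odds ratio 5.97, adjusted p = 0.019) passed Fisher's exact test, which takes IDs as independent. With an estimated correlation (0.73 among chloroplast and 0.63 among mitochondrial IDs), limma's camera gave p = 0.42 for the chloroplast and p = 0.79 for the mitochondrial IDs, and the chloroplast IDs called lower at any fold numbered 0, 1 and 0 without levofloxacin replicate 1, 2 or 3. The Cz18 odds ratio stayed above 1 in each left-out fit but missed the threshold without control replicate 1 (1.73, adjusted p = 0.052) and without levofloxacin replicate 1 (3.20, adjusted p = 0.26), 2 (2.33, adjusted p = 0.051) or 3 (3.36, adjusted p = 0.28).

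**Figure D4:**
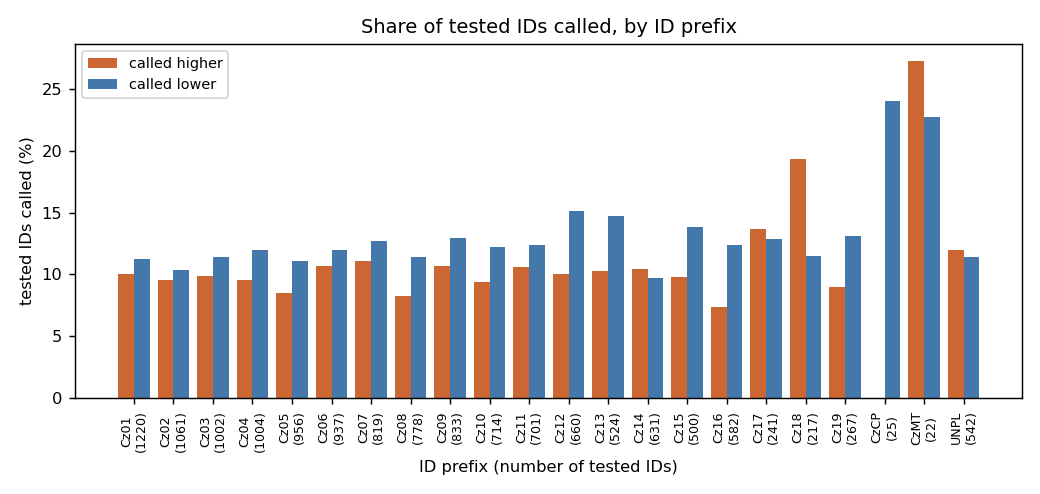
Share of tested IDs called higher and lower (percent, bars from 0) for each ID prefix, with the number of tested IDs in brackets. Cz18 has 19.4% of its IDs called higher, the mitochondrial prefix 27.3%, and the chloroplast prefix has 24% of its IDs called lower and 0 higher.

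Genes next to each other in the ID order changed together more often than chance gives. Of 14214 pairs of adjacent tested IDs, 679 were called in the same direction (317 both higher, 362 both lower), against a mean of 350 and a maximum of 426 in 10000 shuffles (permutation test, one-sided, ratio 1.94, p = 1e-04, the smallest the shuffles can give). Opposite directions occurred in 256 pairs. There were 10 runs of at least 5 adjacent IDs with the same call, against a mean of 0.472 and a maximum of 4 in 1000 shuffles. The ratio fell to 1.26 for IDs 2 places apart and 1.14 for 3 places, and lay between 0.98 and 1.05 from 5 to 100 places apart. For adjacent IDs it was 3.37 without control replicate 3, and 11.2, 4.95 and 13.6 without levofloxacin replicate 1, 2 or 3, where fewer IDs were called.

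**Figure D5:**
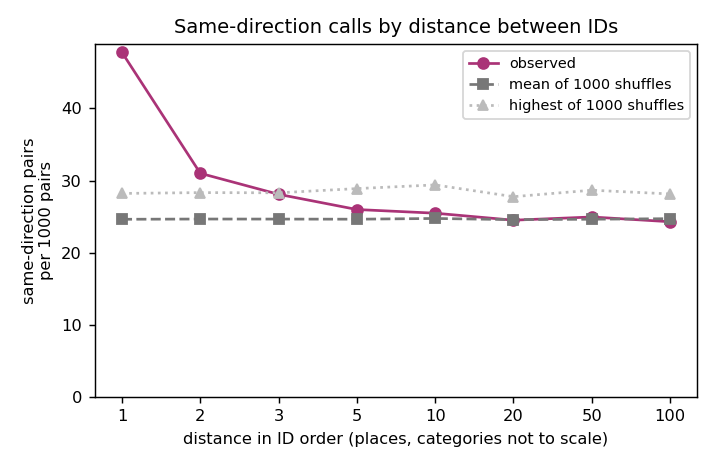
Pairs of tested IDs called in the same direction, per 1000 pairs, against their distance in the ID order (places), with the mean and the highest of 1000 shuffles. The observed value exceeds the highest shuffle at distances 1 and 2.

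IDs that fell had longer coding sequences than the others. Their median coding length was 1320 bases (quartiles 771 and 2265), against 1053 bases (582 and 1713) for IDs that rose and 1053 bases (576 and 1797) for IDs that did not pass. The lower calls differed in coding length from all other tested IDs (permutation test across genes, two-sided, 100000 resamples, p = 1e-05, the smallest they can give). Across all tested IDs the relation of coding length and log2 fold change was weak (Spearman's rho -0.07, across genes, which are not independent replicates).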

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

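The tests of the IDs held by the FPKM table alone were chosen after their values had been seen, and so was the choice to read them ID by ID, since the sum over the 5 IDs lay from 75.8 to 116 FPKM in the controls and from 90.4 to 109 FPKM with levofloxacin and overlapped. For 1 of these 5 IDs, which enter no count test, each levofloxacin library lay above each control: it had 11.5 ± 0.65 FPKM (SD, n = 3) in controls and 12.8 ± 0.63 FPKM with levofloxacin. Chance gives this in 5% of IDs. Among all IDs tested on counts, 45.3% had no overlap between the groups in either direction, so such an ID is not unusual here. The exact permutation test (two-sided) gave p = 0.10, the smallest that 3 against 3 can give, and limma on log2(FPKM + 1) a log2 fold change of 0.15 with an adjusted p = 0.47, so the difference did not pass the threshold. In 2 of the other IDs each levofloxacin library lay below each control, at means under 1 FPKM, and both passed in limma (log2 fold changes on the log2(FPKM + 1) scale of -0.52 and -0.39, adjusted p = 0.025 and 0.046).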

How the results depend on the processing

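The sample weights, and the use on the Cz18 and neighbour results of settings other than DESeq2 and the 2-fold calls, were chosen after the data had been seen. All IDs called in the comparison of 3149 kept their sign wherever they were tested under another normalisation, filter, test or set of libraries. Only 17 of these calls had overlapping groups, so leaving out a library could hardly turn a sign. The kept signs are therefore no measure of how firm the calls are. RLE, upper-quartile and library-total scaling, both other filters, DESeq2 and limma-voom without weights left the counts of changed IDs and of 2-fold changes within 1.5 times of 3149 and 1077. Sample weights in limma-voom raised the changed IDs to 4873 (2339 higher), and an adjusted p under 0.01 lowered them to 432 (186 higher, 246 lower). The changes of at least 2-fold numbered 671 (371 lower) on log2(FPKM + 1), where the pseudocount shrinks the folds of low values, 708 (394 lower) there with a mean FPKM of at least 1, and 197 (68 higher, 129 lower) when edgeR's glmTreat tested against 1.5-fold. With the replicate number as a block, 2878 IDs were called, 2569 of them among the 3149. The labels do not say whether the numbers pair the samples. Correlations between libraries of the same number were all positive (0.16, 0.05 and 0.04), but not every library correlated best with its own number, so pairing stays open. Leaving out each library in turn gave 240 to 4402 changed IDs (102 to 2048 higher, 138 to 2354 lower), 200 to 1681 of at least 2-fold (88 to 577 higher, 112 to 1104 lower) and a Cz18 odds ratio of 1.73 to 3.36. Without levofloxacin replicate 2 more IDs rose than fell (477 and 389, and 249 and 240 at 2-fold), as also among all calls on log2(FPKM + 1) (1204 and 1166). The same held on log2(FPKM + 0.1) (1236 and 1208) and on log2(FPKM + 1) with a mean FPKM of at least 1 (1271 and 1190). Limma-voom without weights gave nearly equal numbers (1411 and 1416). The other normalisations, both other filters and DESeq2 kept more falls than rises. The lowest counts came without a levofloxacin library, which leaves fewer of the less variable samples. The ratio of same-direction neighbours to shuffles was 1.72 to 13.6 over the left-out fits, with the highest values from the smallest sets of calls. The precision was limited by 3 libraries a group and by controls that varied by 24.9%.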

Other observations

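The tests of reads shared by adjacent neighbours, of a common mitochondrial change, of treated material at other folds and against single controls, and of replicate spread among mitochondrial IDs, and the counts by abundance, replicate range and unplaced sequence, were chosen after the data had been seen. The bounds for the tests of the control spread were set with its uncorrected correlation known. Among the 4746 IDs with the lowest mean CPM 601 fell and 323 rose, while among the 4745 with the highest 539 fell and 575 rose. Without levofloxacin replicate 2, 102 fell and 101 rose among the lowest, and 147 fell and 199 rose among the highest. Without levofloxacin replicate 1 these were 29 and 19 among the lowest and 53 and 52 among the highest, and without levofloxacin replicate 3 they were 29 and 18 and 50 and 44. Without control replicate 3 they were 187 and 102 among the lowest and 204 and 233 among the highest, and without control replicate 2 they were 823 and 473 and 762 and 728. IDs that differed by more than 2-fold between replicates numbered 1810 (12.7%) among the controls and 535 (3.76%) among the levofloxacin libraries. The reads on unplaced sequence made up 3.17 to 3.24% of the control libraries and 3.35 to 3.40% of the levofloxacin libraries, without overlap (exact permutation test, two-sided, p = 0.10, the smallest that 3 against 3 can give).

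The control libraries differed from each other along the direction in which they differed from the levofloxacin libraries: control 1 minus control 2 was related to the levofloxacin mean minus control 3, which shares no library with it, with r = -0.47 ± 0.01 (jackknife SE over prefixes; Spearman's rho -0.37, across genes), and the other arrangements gave 0.45 and -0.13, against -0.18 to 0.00 within the levofloxacin group. Thinning all libraries to the smallest total (r = -0.46) and removing a trend in coding length (r = -0.47) left the relation in place. It therefore does not rest on unequal totals or on such a trend. Both tests had little to remove. Totals ran from 28482776 to 36223195 reads, and Spearman's rho of coding length and log2 fold change was -0.07. The relation also stayed without the 100 most abundant IDs (r = -0.47), taken out as points among 14236 with the normalisation unchanged. The relation therefore does not rest on those IDs as points. Their effect through the normalisation was not tested. Treated material in control 2 would put it at a single fraction of the way from controls 1 and 3 to the levofloxacin mean for all genes, but the median fractions were 0.77 for IDs at least 4-fold lower and 0.30 for IDs at least 4-fold higher (gap 0.47 ± 0.045, bootstrap SE), with gaps of 0.35 ± 0.03 at 2 to 4-fold and 0.13 ± 0.02 at 1.5 to 2-fold, which argues against it as the whole cause. From the largest to the smallest folds the gaps were 0.58, 0.30 and 0.05 against control 1 alone and 0.32, 0.20 and 0.08 against control 3 alone, so a smaller contribution of such material stays open. A hypothesis is that the control libraries may come from cultures at different points of a growth or nutrient course that levofloxacin also shifts, which these libraries do not test.

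The opposite changes of mitochondrial IDs argue against a single change shared by all mitochondrial RNA, such as in genome copies or carry-over. At least 5 called IDs went each way, although 1 rose and 3 fell without levofloxacin replicate 1 or 3. The bound for this test was set with the calls known. Selection of transcripts without a tail need not act alike on all of them, so it remains open. As a set the changes exceeded the spread between these libraries. Limma's fry, which keeps the correlation between IDs, gave a mixed adjusted p = 0.00011 and at most 0.0030 without each library. By edgeR 1 ID was called higher and 3 lower in each of the 7 fits, which share most of their libraries. The labels do not say whether the samples are separate cultures, so spread between cultures may not be covered and remains open. The fry test does not compare the set with other genes, and the Cz18 IDs passed it too (fry, mixed adjusted p = 0.0011). Against other IDs, Fisher's exact test was not passed by calls of any fold (adjusted p = 0.27 for higher and 0.55 for lower). It was passed by higher calls of at least 2-fold (adjusted p = 0.00056). A candidate explanation is that levofloxacin, or a difference in culture state that goes with it, alters mitochondrial transcripts individually. It was not tested, and antisense reads remain open because the strand setting is not given.

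The excess of neighbouring IDs called in the same direction was kept when pairs with coding lengths within 10% were left out (618 pairs, ratio 1.91). This argues against tandem copies of like length as the whole cause. Copies that differ in length stayed in and no sequences were compared, so such copies remain open. The excess was also kept when calls were shuffled within abundance deciles (ratio 1.93), which argues against neighbours of similar abundance. Reads shared by overlapping genes were to be excluded by an excess at 2 places apart, which was found (ratio 1.26, above the highest of 10000 shuffles). That bound was wrong, because the excess of adjacent pairs was 3.65 times as high and a value at 2 places does not bear on the remainder. Shared reads therefore cannot be told apart from shared regulation: gene coordinates and strands, which would decide, are not in the tables. Shared regulation of neighbours is a hypothesis and was not tested.

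The 6 libraries can be split into 3 against 3 in 10 ways, too few for a share under 0.05. The real split gave 3149 changed IDs, 1077 of at least 2-fold, 679 same-direction neighbours, 42 higher calls on Cz18 and 11 mitochondrial calls. In each case it was 1 of 10 splits with a value as large, and the highest other split gave 0. Every other split mixed control and levofloxacin libraries in each group, which put the treatment difference into the spread within groups. With 0 IDs called, the neighbour, Cz18 and mitochondrial counts are 0 as well. These results are therefore not separate comparisons, and the 0 is not a measure of chance.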
